A study of Homo sapiens with 24 samples.

How the data were processed

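Total, subpolysomal and polysomal RNA of MCF7 cells was sequenced 48 h after transfection of eIF4A1 siRNAs or control siRNAs, with 4 libraries in each of 6 groups. Per the labels, total RNA was extracted with a phenol-based reagent and the fractions by precipitation with guanidine hydrochloride and ethanol and then lithium chloride, so total and fraction RNA differ in extraction, and libraries followed the TruSeq RNA protocol, second version. The authors' processing notes name Bowtie without a version, and the deposited tables are named as output of mmdiff, a tool that compares models of expression between groups.

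The authors deposited 24 tables, each holding the libraries of a single comparison at the level of genes, transcripts or 5′ UTR groups. The deposited expression values are natural log (ln) estimates corrected for feature length, per the file headers and the values themselves. Other deposited columns give the posterior SD of each value on the same scale and the authors' posterior probability of a difference between groups. Each table was scaled between its own libraries, and the same library differed between tables only by a constant, so tests never mixed tables. The genome build, annotation, strand and filters are not stated. Genes carry Ensembl identifiers, which were matched to symbols of GENCODE release 29 by identifier, with 48670 of 55068 genes given a symbol. Synonyms in the gene lists were resolved with a RefSeq gene table. No sample column was left unmapped, and 9 tables of the same libraries in contrasts or levels not needed were left out.

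No counts or depths are given. The posterior SD of a feature was turned into the reads that would give it under a gamma posterior with an assumed prior shape of 0.1, summed over genes to give the implied reads of a library. For features without reads this assumption gives an SD of 10.1. The 196 genes taken as without reads were picked by their high SD in every library. Their median SD of 10.3 therefore does not test the assumption. These implied reads are estimates from the authors' model and not counts, so no counting interval is given.

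Values were divided by the natural log of 2 to give log2. Features were kept with a mean over the libraries of a table of at least 0 on the natural log scale. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. The comparisons were eIF4A1 against control siRNA within each fraction, and the difference of these changes between each pair of fractions, at the gene level for all pairs and at the transcript and 5′ UTR group level for polysomal against subpolysomal RNA. No block was used in the comparisons given first, because the labels do not say what a shared replicate number means. Whether the numbers, which come from the labels, pair the libraries of the 2 siRNAs was checked by the correlation of deviations from the group means. Over the same-numbered pairs it ran from −0.34 to 0.57 in total, −0.06 to 0.55 in subpolysomal and −0.16 to 0.74 in polysomal RNA. It was highest for number 1 in each fraction, and 2 of 4 pairs in each fraction were under 0.1, so the numbers were not taken as pairs, and fits with a block are given as alternatives. Files were read with the data.table package (version 1.17.8), sequence properties were computed with Python 3.11.15, and figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.

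Before the data were examined, 19 gene lists were fixed: initiation factors, cytosolic ribosomal proteins, other TOP mRNAs, mRNAs sensitive to eIF4A or eIF4E, growth factors and receptors, DNA replication and G1/S, mitosis and G2/M, estrogen response, ATF4 and amino acid response, unfolded protein response, p53 targets, interferon response, cholesterol synthesis, nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, nuclear long noncoding RNAs, small nucleolar RNA host genes, proteasome subunits and non-epithelial cell markers. The lists and the 5′ UTR properties came from general knowledge of eIF4A, which may include published work on these samples, so the lists of sensitive mRNAs and of growth factors and the 5′ UTR properties are not independent evidence of a direction. Some genes are in more than 1 list. Initiation factors include EIF4A1, the siRNA target, which lowers their mean, and were not tested without it. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. With an estimated correlation 0 lists pass in any of the 6 comparisons.

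The rule for named genes was also fixed before the data were examined. It takes EIF4A1, then in each gene-level comparison the 8 higher and 8 lower genes with the largest change among those past the threshold with a symbol, a mean of at least 1 on the natural log scale and, within a fraction, no overlap between the siRNAs, and from each list the 4 members with the smallest p. List members past the threshold were named beyond these where few passed. For transcripts and 5′ UTR groups none passed, so the rule names none.

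For the 5′ UTR comparison, 14040 of 14860 tested transcripts (94.5%) matched GENCODE release 29 by identifier and 11526 had an annotated 5′ UTR, with a median length of 171 bases and a median GC of 67.2%. A score per library compared the top and bottom 25% of length or GC, or transcripts with and without 4 GGC repeats. The plan gave the difference of differences of this score as a value with its SE. The exact permutation p over the 4900 exchanges of labels within fractions, its adjustment over 3 properties and the scores for other parts of the transcript were added after the data were seen. Correlations across libraries used all 40320 pairings, and comparisons of 4 against 4 libraries all 70 exchanges, which allow no p below 0.0286.

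The fits were tested on simulated data with 200 changed genes and noise drawn independently for each gene. The real libraries share deviations across genes, so rates in them may differ. In total, subpolysomal and polysomal RNA, 58.2%, 46.3% and 61.2% of 2-fold changes were recovered, and 32.8%, 55.2% and 40.3% in polysomal against subpolysomal, polysomal against total and subpolysomal against total RNA. False calls in the same order were 4 of 120, 2 of 101 and 9 of 129 calls, and 9 of 88, 7 of 107 and 5 of 102.

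Alternatives fixed before the data were examined were no filter, a mean of at least 1, a posterior SD of at most 0.5, median centring, quantile normalisation, a pseudocount of 1, weights from the posterior SDs, a block for replicate number, a block for each culture number in the differences between fractions, other deposited tables of the same libraries, the authors' posterior probability above 0.5, estimated correlation, EIF4A1 as the sum over its transcripts, a split at the median for the 5′ UTR properties and each library left out. Added after seeing the data were the GC score or the implied reads as covariates, the library with the fewest implied reads of each group left out, 1 library of each siRNA left out together, the coding sequence GC score as a covariate of the 5′ UTR score and slopes fitted together.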

Results

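RNA was sequenced from MCF7 cells, an estrogen receptor-positive human breast cancer line, 48 h after transfection with a pool of siRNAs against eIF4A1 or a non-targeting control pool. eIF4A1 is the helicase of the cap-binding complex that opens structure in 5′ untranslated regions during translation initiation. From each siRNA, 3 kinds of RNA were taken: total RNA, subpolysomal RNA (mRNA carrying few or no ribosomes) and polysomal RNA (mRNA carrying several). Each of the 6 groups held 4 libraries, 24 in all. The deposited values are natural logs of an expression estimate, given here as log2, and the scale of the underlying estimate is not stated. The labels do not say whether the 4 replicates of a group are separate cultures, so p-values measure only the spread between these libraries, which may be technical. Read counts and depths are not given. The reads implied by the deposited posterior SDs, a model-based estimate, ran from 2420000 in control subpolysomal replicate 2 to 10800000 in control subpolysomal replicate 4. They ran from 3110000 to 9290000 in total RNA and from 3510000 to 10100000 in polysomal RNA. The genome build is not stated, so genes are given by symbol without positions.

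EIF4A1 mRNA, the siRNA target, was lower with eIF4A1 siRNA in all 3 kinds of RNA. Its log2 level went from 8.87 ± 0.07 to 5.56 ± 0.29 in total RNA (SD, n = 4 each), which left 10.1% of the control level. In subpolysomal RNA it went from 8.15 ± 0.13 to 4.79 ± 0.25, or 9.74% of control. In polysomal RNA it went from 9.20 ± 0.08 to 5.03 ± 0.52, or 5.56% of control. Levels are set side by side across fractions only as values, since each fraction's table was normalised on its own. The log2 changes were −3.31 ± 0.13 (SE, limma adjusted p = 2.54e-07), −3.36 ± 0.16 (adjusted p = 1.69e-06) and −4.17 ± 0.22 (adjusted p = 9.04e-06) in that order. EIF4A2, the close paralog of EIF4A1, stood at 134%, 103% and 139% of control in total, subpolysomal and polysomal RNA, with log2 differences of 0.41 ± 0.17 (adjusted p = 0.150), 0.05 ± 0.16 (adjusted p = 0.909) and 0.49 ± 0.19 (adjusted p = 0.165). EIF4A1 shares exons with a readthrough gene and sequence with pseudogenes, so reads assigned to it may include theirs.

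**Figure D1:**
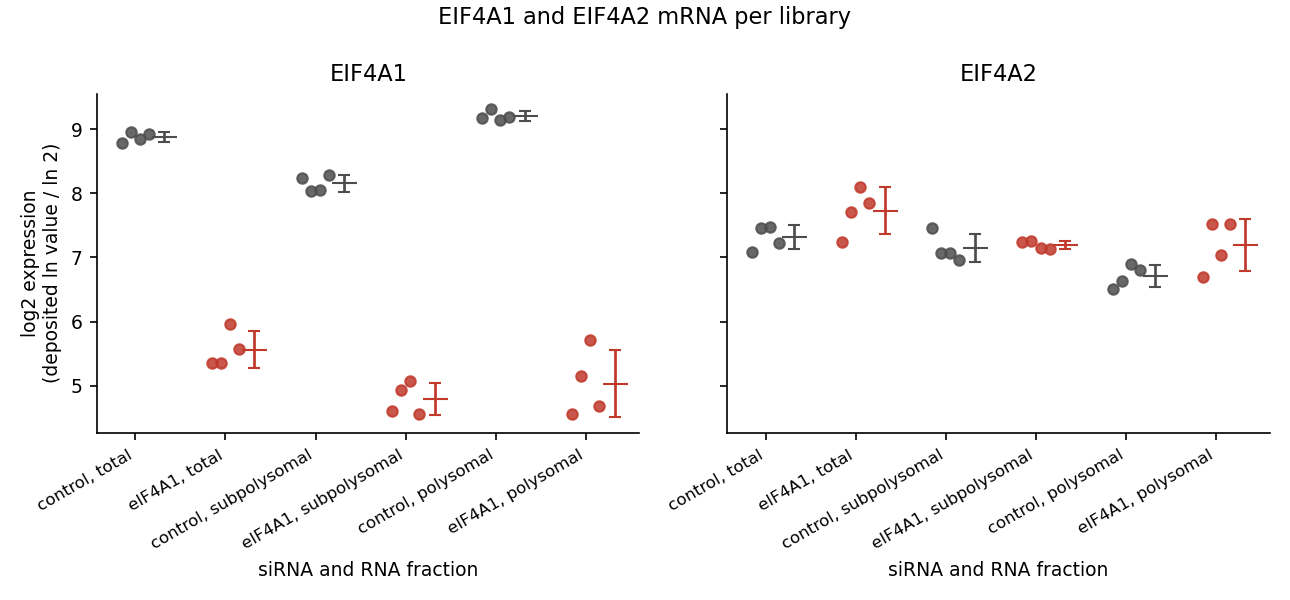
Log2 expression of EIF4A1 and EIF4A2 in each library (points) by siRNA and RNA fraction, with the mean and SD of 4 libraries as bars. Every eIF4A1 siRNA library lies below every control library of its fraction for EIF4A1, with group means of 4.79 to 5.56 against 8.15 to 9.20.

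The first comparison asks which mRNAs differ in total RNA after eIF4A1 knockdown. ID1 and ID3, inhibitors of basic helix-loop-helix transcription factors, rose by 1.45 ± 0.22 (SE, log2, adjusted p = 0.0069) and 1.27 ± 0.28 (adjusted p = 0.025), and CA2, a carbonic anhydrase, rose by 1.28 ± 0.14 (adjusted p = 0.00127). BRINP3 (1.15), PGM1 (1.05), a phosphoglucomutase, and SNHG15 (1.07), a host gene of small nucleolar RNAs, rose as well, as did BCL2L2-PABPN1 (1.44) and TRIM52-AS1 (1.08). Among the genes that fell were PLAC1 (−2.19 ± 0.42, adjusted p = 0.016), INHBE (−1.99 ± 0.36, adjusted p = 0.0129), which encodes a subunit of a TGF-beta family ligand, RIPOR3 (−1.94), AFAP1L2 (−1.91) and the long noncoding RNAs LINC01016 (−1.98) and MIR503HG (−1.63). UGT1A6, a glucuronosyltransferase gene, fell by 1.64 on the log2 scale. The values of BCL2L2-PABPN1, TRIM52-AS1 and UGT1A6 are less certain, because these are a readthrough gene, an antisense gene and a gene with exons shared by its neighbours.

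In total RNA, 4 lists shifted upward by camera with its preset correlation. Of 73 tested nuclear-encoded subunits of the respiratory chain, 8 rose (30 adjusted over the list alone), none fell and 65 did not pass. ATP5MC3 (0.58), ATP5MC1 (0.83) and UQCR10 (0.49) were among them, and the median log2 change of the list was 0.28 (camera adjusted p = 9.85e-13, but adjusted p = 0.286 with an estimated correlation). Of 30 proteasome subunits, 2 rose, PSMA7 (0.45) and PSMC3 (0.38), or 12 adjusted over the list alone, and 28 did not pass. The proteasome median was 0.29 (adjusted p = 1.11e-07, but adjusted p = 0.286 with an estimated correlation). None of the 78 cytosolic ribosomal protein genes passed alone, also adjusted over the list alone, with a list median of 0.11 (adjusted p = 0.00188, but adjusted p = 0.658 with an estimated correlation). Of 34 mitosis and G2/M genes, CDC25B (0.84), a phosphatase that activates CDK1, FOXM1 (0.75) and BUB3 (0.45) rose, the same number adjusted over the list alone, and 31 did not pass. The mitosis list median was 0.09 (adjusted p = 0.0261, but adjusted p = 0.658 with an estimated correlation).

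A further 8 lists shifted downward in total RNA. Of 29 genes of the ATF4 and amino acid response, 8 fell, including DDIT4 (−1.24), SLC7A11 (−1.36), the cystine transporter, STC2 (−1.22) and SLC3A2 (−0.59), while adjusted over the list alone 11 fell and 1 rose. The ATF4 response median was −0.35 (adjusted p = 3.44e-07, but adjusted p = 0.286 with an estimated correlation). Of 25 p53 targets, 5 fell, among them TP53INP1 (−1.54), GDF15 (−1.32), CDKN1A (−0.68) and TNFRSF10B (−0.82), and 1 rose, while adjusted over the list alone 7 fell and 1 rose. The p53 target median was −0.24 (adjusted p = 8.37e-05, but adjusted p = 0.215 with an estimated correlation). Of 43 growth factors and receptors, 7 fell, including RET (−0.70), TGFBR1 (−0.66), FZD6 (−0.66) and FZD4 (−1.08), and 1 rose, while adjusted over the list alone 16 fell and 1 rose. The growth factor median was −0.35 (adjusted p = 4.77e-07, but adjusted p = 0.215 with an estimated correlation). Of 26 genes of cholesterol synthesis, 6 fell, including CYP51A1 (−1.17) and HMGCR (−0.72), the rate-limiting enzyme, and 7 fell adjusted over the list alone. The cholesterol synthesis median was −0.18 (adjusted p = 6.73e-05, but adjusted p = 0.286 with an estimated correlation). Of 30 estrogen response genes, 5 fell, also adjusted over the list alone, including CA12 (−1.11), RET, STC2 and IGFBP4 (−0.63), the last 3 of which are also in other lists. The estrogen response median was −0.22 (adjusted p = 0.000527, but adjusted p = 0.286 with an estimated correlation). HERPUD1 (−0.77) was the 1 gene of 24 in the unfolded protein response that fell, also adjusted over the list alone. The unfolded protein response median was −0.33 (adjusted p = 0.00292, but adjusted p = 0.658 with an estimated correlation). Of 30 mRNAs known as sensitive to eIF4A or eIF4E, 4 fell, PIM1 (−0.81), VEGFA (−0.56), FOS (−0.90) and NRAS (−0.48), while adjusted over the list alone 6 fell and 2 rose. The eIF4A-sensitive mRNA median was −0.16 (adjusted p = 0.0261, but adjusted p = 0.215 with an estimated correlation). Of 5 nuclear long noncoding RNAs, NEAT1 (−0.89) and FTX (−1.10) fell, and 4 fell adjusted over the list alone. The nuclear noncoding RNA median was −0.62 (adjusted p = 0.00824, but adjusted p = 0.286 with an estimated correlation), and −0.08 over 8 members with no filter (adjusted p = 0.00495).

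The 6 other lists tested in total RNA did not pass the group test. Of them, DNA replication and G1/S passed without control replicate 1 (adjusted p = 0.0368), control replicate 3 (0.0143) or eIF4A1 replicate 2 (0.0383), and the interferon response with no filter (0.0349). Median log2 changes were 0.07 for 33 initiation factors (adjusted p = 0.426), 0.03 for 13 other mRNAs with a terminal oligopyrimidine (TOP) start (adjusted p = 0.904), 0.08 for 43 DNA replication and G1/S genes (adjusted p = 0.122), 0.14 for 19 interferon response genes (adjusted p = 0.207), 0.01 for 13 mitochondrially encoded mRNAs (adjusted p = 0.946) and −0.02 for 11 host genes of small nucleolar RNAs (adjusted p = 0.904). With an estimated correlation their adjusted p values were 0.58 or more. Within them, IFI6 (0.88), IFIH1 (0.91) and USP18 (0.74) of the interferon response, DHX29 (0.58) of the initiation factors, POLA2 (0.55) and SNHG7 (0.61) rose, and EPB41L4A-AS1 (−0.74) fell besides EIF4A1. The initiation factors, EIF4A1 included, had a mean of −0.00 and the small nucleolar RNA hosts a median of −0.02, both with a test direction of up. Of 20 markers of non-epithelial cells, 4 were expressed enough to be tested in total RNA, COL3A1 (−0.32), ACTA2 (−0.43), COL1A1 (−0.14) and HBA1 (0.38), none passed, and so short a list was given no group test. In subpolysomal RNA 2 of these markers were tested and in polysomal RNA 4, again with none past the threshold. Adjusted over the list alone, 1 fell in subpolysomal RNA and 0 changed in polysomal RNA, where all 4 had negative changes (median −0.466).

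In all, 782 of 12878 genes tested differed in total RNA (limma, adjusted p under 0.05), 351 higher and 431 lower. The share of rises was 44.9%, and it ran from 10.4% to 52.5% over 20 alternatives, with 1082 rises and 995 falls without eIF4A1 replicate 1 and 47 and 151 without eIF4A1 replicate 4. Among all genes tested, called or not, the 4 libraries of each siRNA did not overlap in 1892 (14.7%), where chance gives 2.86%. The median size of the called changes was 0.69 on the log2 scale, and the authors' deposited posterior probability exceeded 0.5 for 146 genes, 137 of them among the 782. The count was 328, 447, 208 and 204 without control replicate 1, 2, 3 and 4, and 2077, 219, 512 and 198 without eIF4A1 replicate 1, 2, 3 and 4. With a replicate block it was 1324. Of 56 named results in total RNA, 33 fell short of the threshold without at least 1 library. DHX29, PGM1 and PSMC3 fell short in 11 of 20 alternatives, USP18 in 10, SNHG15 in 9 and BRINP3 in 8. List calls ended for the unfolded protein response without control replicate 2 (adjusted p = 0.0691) or eIF4A1 replicate 1 (0.328), for ribosomal proteins (0.0607) and eIF4A-sensitive mRNAs (0.0611) without eIF4A1 replicate 3, and for mitosis without control replicate 1 (0.622), eIF4A1 replicate 3 (0.0839) or eIF4A1 replicate 4 (0.178). The mitosis call also ended with a mean of at least 1 (0.0503), under quantile normalisation (0.06) and with the GC score (0.424) or the implied reads (0.324) as a covariate. Its median was 0.16, 0.14 and 0.19 without control replicate 2, control replicate 3 and eIF4A1 replicate 1, and the ribosomal protein median was 0.18 without control replicate 1.

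**Figure D2:**
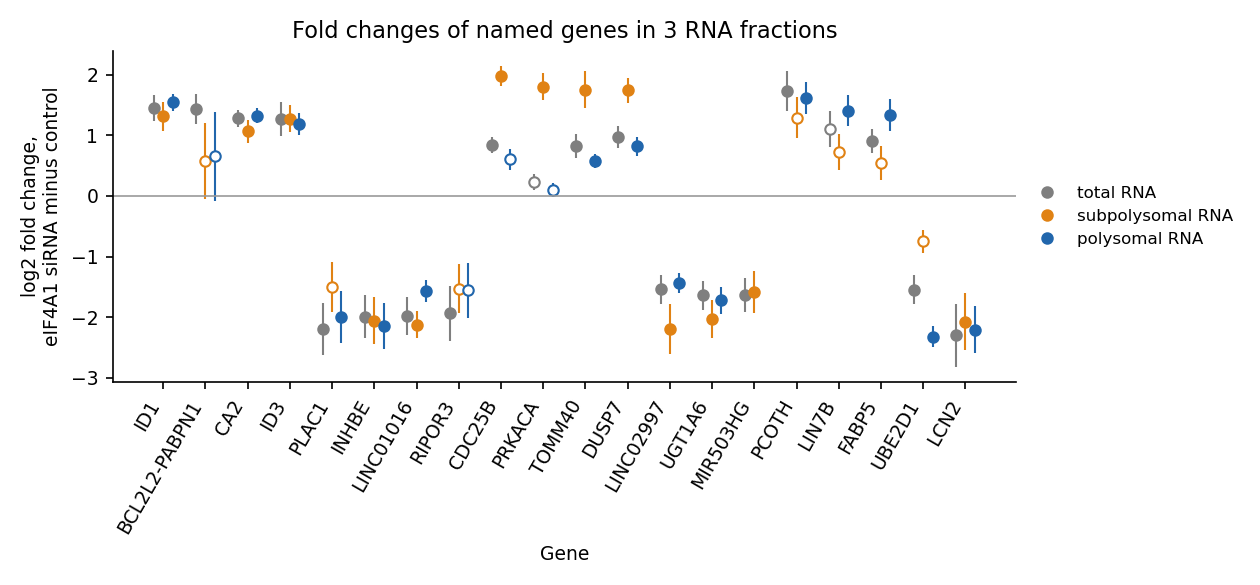
Log2 fold change (eIF4A1 siRNA minus control, with SE bars, 4 libraries per siRNA) in total, subpolysomal and polysomal RNA for the 4 genes with the largest rise and the 4 with the largest fall named in each fraction, EIF4A1 left out. Filled points passed an adjusted p of 0.05 and open points did not, and genes not tested in a fraction have no point; CDC25B lies at 1.98 in subpolysomal, 0.84 in total and 0.60 in polysomal RNA.

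The second comparison asks the same of subpolysomal RNA. Rises were the more frequent here. CDC25B rose by 1.98 ± 0.17 (SE, adjusted p = 0.000434), PRKACA, the catalytic subunit of protein kinase A, by 1.80 ± 0.22 (adjusted p = 0.00398), TOMM40, the channel of the mitochondrial import complex, by 1.75 ± 0.31 (adjusted p = 0.0141) and DUSP7, a MAP kinase phosphatase, by 1.74 ± 0.21 (adjusted p = 0.00365). GIT1 (1.72), the kinase BRAF (1.71), the mitochondrial malic enzyme ME2 (1.61) and DCAF10 (1.59) rose too. Genes that fell included OSTC (−1.47 ± 0.16, adjusted p = 0.00256), a subunit of the oligosaccharyltransferase, GDF15 (−1.43 ± 0.18, adjusted p = 0.00501), a TGF-beta family cytokine, SNX10 (−1.39), UGT1A6 (−2.02) and the long noncoding RNAs LINC02997 (−2.19), LINC01016 (−2.13) and MIR503HG (−1.59).

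Of the lists, 4 shifted in subpolysomal RNA, all downward. In the ATF4 and amino acid response, 3 of 28 genes fell, DDIT3 (−1.29), DDIT4 (−1.23) and STC2 (−1.05), or 7 adjusted over the list alone. The ATF4 response median was −0.40 (camera adjusted p = 1.21e-05, but adjusted p = 0.425 with an estimated correlation). Of 25 p53 targets, GDF15, TP53INP1 (−1.37), CDKN1A (−0.71) and GADD45A (−0.92) fell, or 6 adjusted over the list alone. The p53 target median was −0.31 (adjusted p = 4.91e-05, but adjusted p = 0.177 with an estimated correlation). None of 24 unfolded protein response genes passed alone, also adjusted over the list alone. The unfolded protein response median was −0.27 (adjusted p = 0.0125, but adjusted p = 0.766 with an estimated correlation). Of 26 cholesterol synthesis genes, CYP51A1 (−1.18) fell, or 2 adjusted over the list alone. The cholesterol synthesis median was −0.17 (adjusted p = 0.0125, but adjusted p = 0.437 with an estimated correlation). The other 14 lists tested had adjusted p values of 0.0945 or more. In them, CCNE1 (1.34) and CCND3 (1.06), cyclins of the G1 phase, E2F1 (1.06), EIF4G1 (0.79), the scaffold of the cap-binding complex, LRP5 (0.68) and ABCA3 (1.03) rose, and FOS (−1.22), FGF13 (−1.09) and CA12 (−0.99) fell. The mitosis list had a median of −0.08 but a mean of 0.05 and a test direction of up (adjusted p = 0.883).

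In subpolysomal RNA, 441 of 11719 genes differed (limma), 300 higher and 141 lower, with a share of rises of 68% that ran from 52.4% to 76.2% over 20 alternatives. Among all genes tested, called or not, the siRNAs did not overlap in 1566 (13.4%), where chance gives 2.86%. The median size of the called changes was 0.99, and the authors' deposited posterior probability exceeded 0.5 for 152 genes, 144 of them among the 441. The count was 195, 299, 118 and 143 without control replicate 1, 2, 3 and 4, and 848, 71, 342 and 94 without eIF4A1 replicate 1, 2, 3 and 4. With a replicate block it was 916, and 11 lists passed in place of 4. Of 31 named results in subpolysomal RNA, 19 fell short of the threshold without at least 1 library, and E2F1 fell short in 10 of 20 alternatives. List calls ended for the unfolded protein response without control replicate 2 (adjusted p = 0.121) or eIF4A1 replicate 1 (0.402), and for cholesterol synthesis without eIF4A1 replicate 4 (0.0686). The unfolded protein response median was −0.47 and −0.41 without control replicate 1 and eIF4A1 replicate 2, and the cholesterol synthesis median −0.10 without control replicate 2. Other lists passed without 1 library: the respiratory chain without control replicate 1 (adjusted p = 0.0118) or eIF4A1 replicate 2 (0.00744), cytosolic ribosomal proteins (0.00111 and 2.18e-05) and other TOP mRNAs (0.0182 and 0.00304) without control replicate 2 or eIF4A1 replicate 1, and initiation factors without eIF4A1 replicate 1 (0.0418). The initiation factors included EIF4A1. Estrogen response passed without control replicate 2 (0.035) or eIF4A1 replicate 3 (0.0477), and nuclear long noncoding RNAs without control replicate 4 (0.0406) or eIF4A1 replicate 1 (0.0418).

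The third comparison asks the same of polysomal RNA. UBE2D1, a ubiquitin-conjugating enzyme, fell by 2.32 ± 0.17 on the log2 scale (SE, adjusted p = 0.000219), LCN2, which binds iron-carrying siderophores, by 2.21 ± 0.39 (adjusted p = 0.0147), TP53INP1 by 1.78 ± 0.16 (adjusted p = 0.000421) and the RNA-binding protein gene RBM24 by 1.77 ± 0.15 (adjusted p = 0.000359). INHBE (−2.14), PLAC1 (−1.99) and UGT1A6 (−1.72) fell too. Genes that rose included ID1 (1.54 ± 0.15, adjusted p = 0.000507), CA2 (1.32 ± 0.12, adjusted p = 0.000372), EDN1 (1.24 ± 0.18, adjusted p = 0.0062), which encodes endothelin, the fatty acid-binding protein gene FABP5 (1.33), LIN7B (1.41), PCOTH (1.61), MIR99AHG (1.33) and DGUOK-AS1 (1.29). DGUOK-AS1 is an antisense gene, so its value is less certain.

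In polysomal RNA, 5 lists rose. Of 78 cytosolic ribosomal protein genes, 4 rose, RPL27A (0.55), RPL14 (0.52), RPL41 (0.51) and RPS7 (0.48), or 18 adjusted over the list alone, and 74 did not pass. The ribosomal protein median was 0.29 (camera adjusted p = 3.85e-15, but adjusted p = 0.262 with an estimated correlation). Of 73 respiratory chain subunits, ATP5MC1 (0.75), UQCRC2 (0.58) and ATP5PB (0.50) rose, the same number adjusted over the list alone. The respiratory chain median was 0.26 (adjusted p = 5.28e-10, but adjusted p = 0.262 with an estimated correlation). No member passed alone, also adjusted over the list alone, among 30 proteasome subunits (median 0.24, adjusted p = 3.6e-06, but adjusted p = 0.262 with an estimated correlation), 34 mitosis and G2/M genes (median 0.16, adjusted p = 0.00396, but adjusted p = 0.526 with an estimated correlation) and 13 mitochondrially encoded mRNAs (median 0.26, adjusted p = 0.0196, but adjusted p = 0.558 with an estimated correlation).

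A further 7 lists fell in polysomal RNA. Of 29 ATF4 and amino acid response genes, 5 fell, including SLC7A11 (−1.56), STC2 (−1.15), SLC3A2 (−0.88) and DDIT4 (−1.36), or 9 adjusted over the list alone. The ATF4 response median was −0.39 (adjusted p = 1.22e-07, but adjusted p = 0.264 with an estimated correlation). Of 41 growth factors and receptors, 7 fell, including FZD4 (−1.24), FZD6 (−0.73), VEGFB (−0.89) and TGFBR2 (−0.79), and 1 rose, while adjusted over the list alone 13 fell and 1 rose. The growth factor median was −0.38 (adjusted p = 3.71e-06, but adjusted p = 0.262 with an estimated correlation). Of 25 p53 targets, TP53INP1, TNFRSF10B (−1.03), GDF15 (−1.40) and CDKN1A (−0.81) fell, or 10 adjusted over the list alone. The p53 target median was −0.31 (adjusted p = 3.36e-05, but adjusted p = 0.252 with an estimated correlation). Of 26 cholesterol synthesis genes, CYP51A1 (−1.26) and HMGCR (−0.98) fell, or 5 adjusted over the list alone. The cholesterol synthesis median was −0.24 (adjusted p = 0.000139, but adjusted p = 0.264 with an estimated correlation). Of 30 estrogen response genes, 4 fell, CA12 (−1.27), STC2, RET (−0.71) and CXCL12 (−0.51), or 5 adjusted over the list alone. The estrogen response median was −0.21 (adjusted p = 0.000972, but adjusted p = 0.262 with an estimated correlation). HERPUD1 (−0.87) and EDEM1 (−0.76) of 24 unfolded protein response genes fell, the same number adjusted over the list alone. The unfolded protein response median was −0.32 (adjusted p = 0.00212, but adjusted p = 0.526 with an estimated correlation). Of 30 mRNAs sensitive to eIF4A or eIF4E, NRAS (−0.63), TGFB1 (−0.89) and BCL2 (−1.02) fell, while adjusted over the list alone 4 fell and 1 rose. The eIF4A-sensitive mRNA median was −0.15 (adjusted p = 0.0334, but adjusted p = 0.262 with an estimated correlation). The other 6 lists tested had adjusted p values of 0.0824 or more. In them, USP18 (0.69), IFIH1 (1.03) and SNHG15 (1.10) rose, and EIF4EBP2 (adjusted p = 0.00509), a repressor of the cap-binding protein eIF4E, fell besides EIF4A1. The initiation factors, EIF4A1 included, had a median of 0.15 but a mean of −0.04. The hosts of small nucleolar RNAs had a median of −0.04 but a mean of 0.05, both lists with a test direction of up.

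In polysomal RNA, 483 of 12449 genes differed (limma), 155 higher and 328 lower, with a share of rises of 32.1% that ran from 6.8% to 48.3% over 20 alternatives and was 14.4% without control replicate 4. Among all genes tested, called or not, the siRNAs did not overlap in 1759 (14.1%), where chance gives 2.86%. The median size of the called changes was 0.82, and the authors' deposited posterior probability exceeded 0.5 for 179 genes, 170 of them among the 483. The count was 244, 208, 111 and 97 without control replicate 1, 2, 3 and 4, and 1033, 202, 517 and 146 without eIF4A1 replicate 1, 2, 3 and 4. With a replicate block it was 1330. Of 47 named results in polysomal RNA, 31 fell short of the threshold without at least 1 library, and CXCL12 fell short in 11 of 20 alternatives. List calls ended for the unfolded protein response without eIF4A1 replicate 1 (adjusted p = 0.204), for mitosis without control replicate 1 (0.215) or eIF4A1 replicate 4 (0.052), for eIF4A-sensitive mRNAs without control replicate 4 (0.0505), eIF4A1 replicate 1 (0.0778) or eIF4A1 replicate 4 (0.052), and for mitochondrially encoded mRNAs without eIF4A1 replicate 1 (0.0778) or 2 (0.506) and under quantile normalisation (0.475). Without eIF4A1 replicate 2 the medians of growth factors, estrogen response and cholesterol synthesis were −0.21, −0.13 and −0.10. The cholesterol synthesis median was −0.14 without control replicate 1 and −0.15 without eIF4A1 replicate 4. Other medians were −0.49 for the unfolded protein response without control replicate 1, 0.27 for mitosis without eIF4A1 replicate 1 and 0.43 for mitochondrially encoded mRNAs without eIF4A1 replicate 3. The interferon response passed without control replicate 2 (0.0367) or eIF4A1 replicate 2 (0.0145), and DNA replication and G1/S without eIF4A1 replicate 2 (0.0397).

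**Figure D3:**
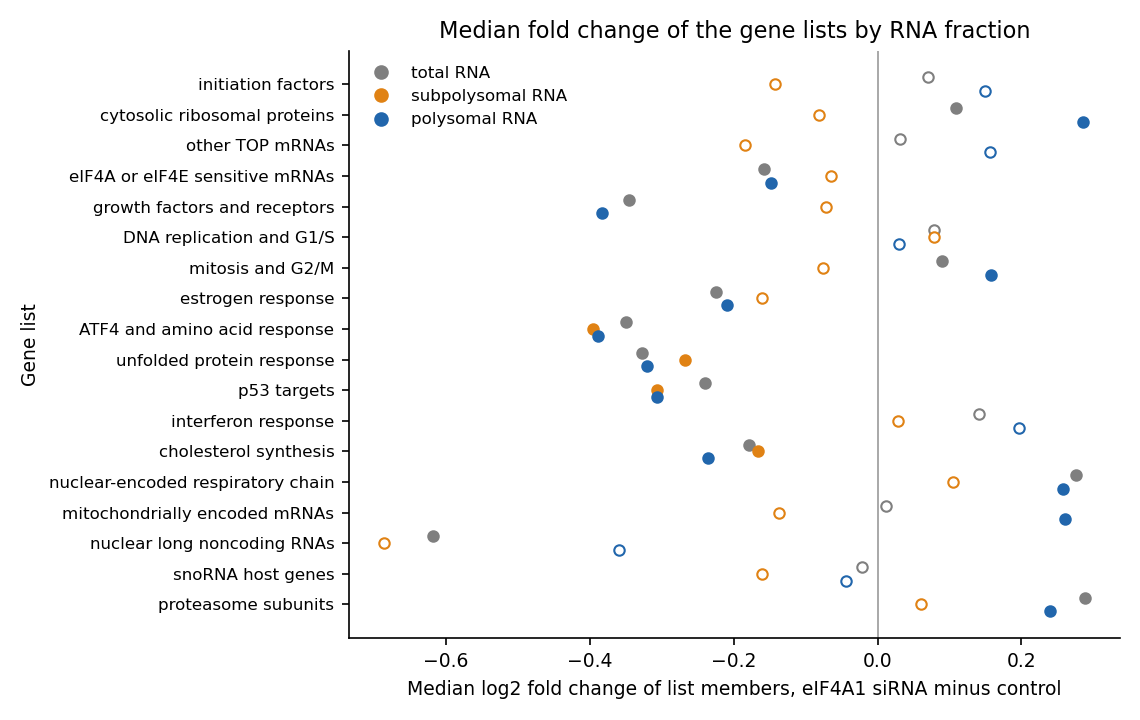
Median log2 fold change (eIF4A1 siRNA minus control) of the tested members of 18 gene lists in total, subpolysomal and polysomal RNA. Filled points passed camera with its preset correlation (adjusted p under 0.05) and open points did not, and 0 lists pass with an estimated correlation; the ATF4 and amino acid response lies at −0.35, −0.40 and −0.39 and nuclear-encoded respiratory chain genes at 0.28, 0.11 and 0.26 in total, subpolysomal and polysomal RNA.

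Changes in the 3 fractions overlapped. Of 12281 genes tested in both total and polysomal RNA, 81 rose in both, where chance would give 4.4, and 227 fell in both, where chance would give 11.1. Total and subpolysomal RNA shared 99 rises (8.9 by chance) and 98 falls (4.9 by chance) among 11554 genes, and subpolysomal and polysomal RNA shared 34 rises (3.9 by chance) and 88 falls (3.7 by chance) among 11400. In each pair, 0 genes changed in opposite directions. The chance counts assume that the fractions are independent. Same-numbered libraries of a siRNA correlated across fractions with r from −0.22 to 0.62 in their deviations from the group means, so part of the overlap may come from shared cultures and not from the siRNA. Across genes, which are not independent replicates, fold changes correlated with r = 0.77 between total and polysomal RNA, 0.595 between total and subpolysomal RNA and 0.558 between subpolysomal and polysomal RNA.

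The fourth comparison asks which mRNAs moved between polysomal and subpolysomal RNA after knockdown, as the difference between the changes in the fractions. In 4 genes, 0 toward and 4 away from the polysomes, it passed the threshold. With no filter 3 genes passed toward and 2 away, with 1 of the 4 among them, and under quantile normalisation 2 toward and 7 away. PRKACA had a difference of −1.68 ± 0.26 (SE, log2), with a change of 0.12 in polysomal and 1.80 in subpolysomal RNA. UBE2D1 had a difference of −1.54 ± 0.25, with changes of −2.29 and −0.75. CCNI, which encodes cyclin I, had −1.15 ± 0.19, with changes of −0.23 and 0.92, and CASC3, a core component of the exon junction complex, had −1.11 ± 0.19, with changes of 0.38 and 1.49. Each had an adjusted p of 0.0394 (limma, 4 libraries in each of 4 groups), and 0 genes passed with a block by culture number, which takes same-numbered libraries of a siRNA as pairs across fractions, while 10 passed with a replicate block. For EIF4A1 the difference was −0.78 ± 0.27 (adjusted p = 0.522), and it ran from −1.954 to −0.628 over 28 alternatives.

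Toward the polysomes, 7 lists shifted in this comparison. All 78 cytosolic ribosomal protein mRNAs had a positive difference, with a median of 0.42 (camera adjusted p = 4.61e-12, but adjusted p = 0.545 with an estimated correlation) and values such as 0.82 ± 0.28 for RPL21 and 0.73 ± 0.28 for RPL27A. All 12 other TOP mRNAs did too (median 0.40, adjusted p = 0.000323, but adjusted p = 0.545 with an estimated correlation), among them NPM1 (0.66) and PABPC4 (0.52), as did all 13 mitochondrially encoded mRNAs (median 0.46, adjusted p = 0.000323, but adjusted p = 0.545 with an estimated correlation), such as MT-ATP8 (0.82). Members of these lists varied together, with estimated correlations of 0.807, 0.694 and 0.809, so they are not separate evidence. For the list mean per library, the exact permutation p was 0.208 for ribosomal proteins and 0.12 for mitochondrially encoded mRNAs. The medians were 0.19 for the nuclear-encoded respiratory chain (adjusted p = 0.000323) and 0.23 for proteasome subunits (0.00609). They were 0.24 for initiation factors (0.0169) and 0.18 for mitosis and G2/M genes (0.0387). In this order, an estimated correlation gave adjusted p values of 0.545, 0.545, 0.545 and 0.662. Growth factors and receptors shifted away from the polysomes, with a median of −0.28 (adjusted p = 0.000323, but adjusted p = 0.545 with an estimated correlation) and −1.08 ± 0.31 for TGFB1. The other 10 lists tested had adjusted p values of 0.106 or more, and mRNAs sensitive to eIF4A or eIF4E had a median of 0.01, a mean of −0.06 and a test direction of down (adjusted p = 0.475). Median, mean and test also differed in sign for the unfolded protein response (0.03, −0.03, up) and p53 targets (−0.04, 0.02, up). No list member passed over all genes, while adjusted over the list alone 3 eIF4A-sensitive mRNAs, 1 mitosis gene and 1 estrogen response gene were lower and none was higher.

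In this comparison 12090 genes were tested, 829 had an unadjusted p under 0.05, and the authors' deposited posterior probability exceeded 0.5 for 52, which include the 4. Without any change, a share of 0.05 of the features tested would have an unadjusted p under 0.05, here and in the comparisons below. The count was 0 without any 1 of the 4 control polysomal libraries, eIF4A1 polysomal replicate 2, 3 or 4, control subpolysomal replicate 3 or 4, or eIF4A1 subpolysomal replicate 2 or 4, and it was 8, 2, 1 and 10 without eIF4A1 polysomal replicate 1, control subpolysomal replicate 1, eIF4A1 subpolysomal replicate 1 and eIF4A1 subpolysomal replicate 3. Without control subpolysomal replicate 1 the ribosomal protein median was 0.22 (adjusted p = 0.000192) and the other TOP median 0.23 (adjusted p = 0.0135), and under quantile normalisation the mitochondrially encoded median was 0.06 (adjusted p = 0.399), the other TOP median 0.21 (adjusted p = 0.0296) and the initiation factor median 0.14 (adjusted p = 0.0296). The mitochondrially encoded median was 0.22 (adjusted p = 0.0445) without eIF4A1 polysomal replicate 2, and the growth factor median −0.18 (adjusted p = 0.00557) without control subpolysomal replicate 2. Without eIF4A1 polysomal replicate 4 the calls of initiation factors (adjusted p = 0.073) and proteasome subunits (0.0519) ended, and without eIF4A1 subpolysomal replicate 3 both did (0.0705 each). The initiation factor call also ended without control subpolysomal replicate 1 (0.0612), the proteasome call without control subpolysomal replicate 2 (0.119) and the respiratory chain call without eIF4A1 polysomal replicate 1 (0.0529). The mitosis call ended without control polysomal replicate 1 (0.539), eIF4A1 polysomal replicate 2 (0.0945) or 4 (0.27), control subpolysomal replicate 2 (0.497) or 4 (0.126), and eIF4A1 subpolysomal replicate 1 (0.169) or 3 (0.131), and its median was 0.29 without control subpolysomal replicate 1. Small nucleolar RNA hosts passed without control polysomal replicate 2 (0.0489) or eIF4A1 subpolysomal replicate 1 (0.00269). With a replicate block they passed too (0.0397), as did nuclear long noncoding RNAs (0.0334). Estrogen response passed, downward, under quantile normalisation (median −0.159, adjusted p = 0.0296) and with no filter (0.0261).

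The comparisons of polysomal with total and of subpolysomal with total RNA share their libraries with the one above. In polysomal against total RNA, 0 of 12587 genes passed (limma), 203 had an unadjusted p under 0.05 and 3 had a deposited posterior probability of the authors above 0.5. Of the lists, 3 shifted toward the polysomes: cytosolic ribosomal proteins (median 0.21, adjusted p = 7.99e-22, but adjusted p = 0.361 with an estimated correlation), other TOP mRNAs (0.09, adjusted p = 0.00511, but adjusted p = 0.361 with an estimated correlation) and mitochondrially encoded mRNAs (0.31, adjusted p = 3.25e-05, but adjusted p = 0.756 with an estimated correlation). EIF4A1 had a difference of −0.84 ± 0.27, with an adjusted p of 1. The other 15 lists had adjusted p values of 0.0549 or more, and median, mean and test differed in sign for initiation factors (0.03, −0.02, down), DNA replication genes (−0.02, 0.00, down), eIF4A-sensitive mRNAs (0.02, 0.02, down) and growth factors (0.02, 0.01, down). The other TOP call ended without eIF4A1 polysomal replicate 4 (adjusted p = 0.0963) or eIF4A1 total replicate 2 (0.0706) and the mitochondrial call without eIF4A1 polysomal replicate 2 (0.475), and under quantile normalisation these calls had adjusted p values of 0.241 and 0.59. The other TOP median was 0.14, 0.18 and 0.16 without control polysomal replicate 1, eIF4A1 polysomal replicate 3 and eIF4A1 total replicate 3. Nuclear long noncoding RNAs (median 0.45) passed, upward, without control polysomal replicate 3 (0.0236), eIF4A1 polysomal replicate 1 (0.0471), 3 (0.0461) or 4 (0.021), control total replicate 1 (0.0499) or 4 (0.0448), or eIF4A1 total replicate 1 (0.00538) or 3 (0.0381). They also passed with a mean of at least 1 (0.0391) and with a pseudocount of 1 (0.0464). The unfolded protein response passed without control polysomal replicate 1 (0.00554), control total replicate 2 (0.0238) or eIF4A1 total replicate 1 (0.00286). The ATF4 response passed without control polysomal replicate 3 (0.0108), eIF4A1 polysomal replicate 1 (0.0331) or control total replicate 2 (0.0238). The respiratory chain passed without eIF4A1 polysomal replicate 1 (0.0386) or eIF4A1 total replicate 1 (0.0172), proteasome subunits without the latter (0.00538) and mitosis without control total replicate 1 (0.00239).

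In subpolysomal against total RNA, 0 of 12271 genes passed (limma), 756 had an unadjusted p under 0.05 and the authors' deposited posterior probability exceeded 0.5 for 22. With a block by culture number 3 genes passed. Growth factors and receptors shifted toward the subpolysomal fraction (median 0.24, adjusted p = 0.000178, but adjusted p = 0.747 with an estimated correlation). Shifted away from it were initiation factors (−0.28, adjusted p = 0.00414), cytosolic ribosomal proteins (−0.21, 0.000393) and other TOP mRNAs (−0.27, 0.0048). So were the respiratory chain (−0.22, 6.17e-05) and proteasome subunits (−0.20, 0.000393). In this order, an estimated correlation gave adjusted p values of 0.747, 0.792, 0.747, 0.747 and 0.747. EIF4A1 had a difference of −0.07 ± 0.20 (adjusted p = 0.975), which was 0.56 under quantile normalisation and 0.06 without eIF4A1 total replicate 3. The other 12 lists had adjusted p values of 0.131 or more, and median, mean and test differed in sign for DNA replication genes (−0.05, 0.00, up) and p53 targets (0.01, −0.07, down). The ribosomal protein call ended without control subpolysomal replicate 1 (adjusted p = 0.707) or eIF4A1 subpolysomal replicate 4 (0.062), and the other TOP call without control subpolysomal replicate 1 (0.22) and under quantile normalisation (0.105). The ribosomal protein median was −0.37, −0.44 and −0.14 without control subpolysomal replicate 2, eIF4A1 subpolysomal replicate 1 and eIF4A1 subpolysomal replicate 3, and −0.10 under quantile normalisation (adjusted p = 3.28e-05). Other TOP mRNAs had a median of −0.45 without eIF4A1 subpolysomal replicate 1. Mitosis passed, downward, without control subpolysomal replicate 1 (0.00148), eIF4A1 subpolysomal replicate 4 (0.0391), control total replicate 2 (0.0339) or 3 (0.0431), or eIF4A1 total replicate 1 (0.016). Mitochondrially encoded mRNAs passed without control subpolysomal replicate 2 (0.029), eIF4A1 subpolysomal replicate 1 (0.0316) or eIF4A1 total replicate 2 (0.0396), small nucleolar RNA hosts without eIF4A1 subpolysomal replicate 1 (0.00333) and the unfolded protein response without eIF4A1 total replicate 1 (0.0365).

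The same question was asked of single transcripts and of groups of transcripts sharing a 5′ untranslated region (5′ UTR). Of 14860 transcripts tested between polysomal and subpolysomal RNA, 0 passed (limma, smallest adjusted p 0.108), 799 had an unadjusted p under 0.05 and the authors' deposited posterior probability exceeded 0.5 for 49. Of 17437 groups, 0 passed (limma, smallest adjusted p 0.113), 947 had an unadjusted p under 0.05 and the authors' deposited posterior probability exceeded 0.5 for 52. In simulated data of this design, with noise independent between features, a 2-fold change was recovered in 6% of changed transcripts and 3% of changed groups and a 4-fold change in 34.8% and 47%, so changes of these sizes could be missed. False calls were 3 of 30 for transcripts and 0 of 33 for groups.

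The last comparison asks whether 5′ UTR properties go with the shift between polysomal and subpolysomal RNA. Each library was scored as the mean log2 level of transcripts in the top 25% of a property minus that in the bottom 25%. Transcripts with GC-rich 5′ UTRs had a score difference of −0.46 ± 0.18 (SE), that is, toward subpolysomal relative to polysomal RNA after knockdown (two-sided exact permutation p = 0.0298, adjusted over 3 properties p = 0.0894), which does not pass the threshold. The group means of this score were 0.24 ± 0.13 with eIF4A1 siRNA and −0.18 ± 0.24 with control in subpolysomal RNA (SD, n = 4), and −0.05 ± 0.17 and −0.00 ± 0.14 in polysomal RNA. Long 5′ UTRs had a difference of −0.04 ± 0.12 (exact permutation p = 0.747, adjusted p = 0.747), and 497 transcripts with 4 GGC repeats in the 5′ UTR had −0.13 ± 0.10 (exact permutation p = 0.251, adjusted p = 0.376). The GC of the coding sequence, 3′ UTR and whole transcript gave −0.40 ± 0.45, −0.39 ± 0.46 and −0.50 ± 0.56. In this order, exact permutation p was 0.366, 0.402 and 0.378, and all were added after the data were seen. Across 11526 transcripts, which are not independent replicates, Spearman's rho of the shift was close for the GC of all parts, at −0.23 for the 5′ UTR, −0.194 for the coding sequence, −0.181 for the 3′ UTR and −0.215 for the whole transcript. Without control subpolysomal replicate 2, the library with the fewest implied reads, the 5′ UTR GC difference was −0.31 ± 0.15 (exact permutation p = 0.0637).

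**Figure D4:**
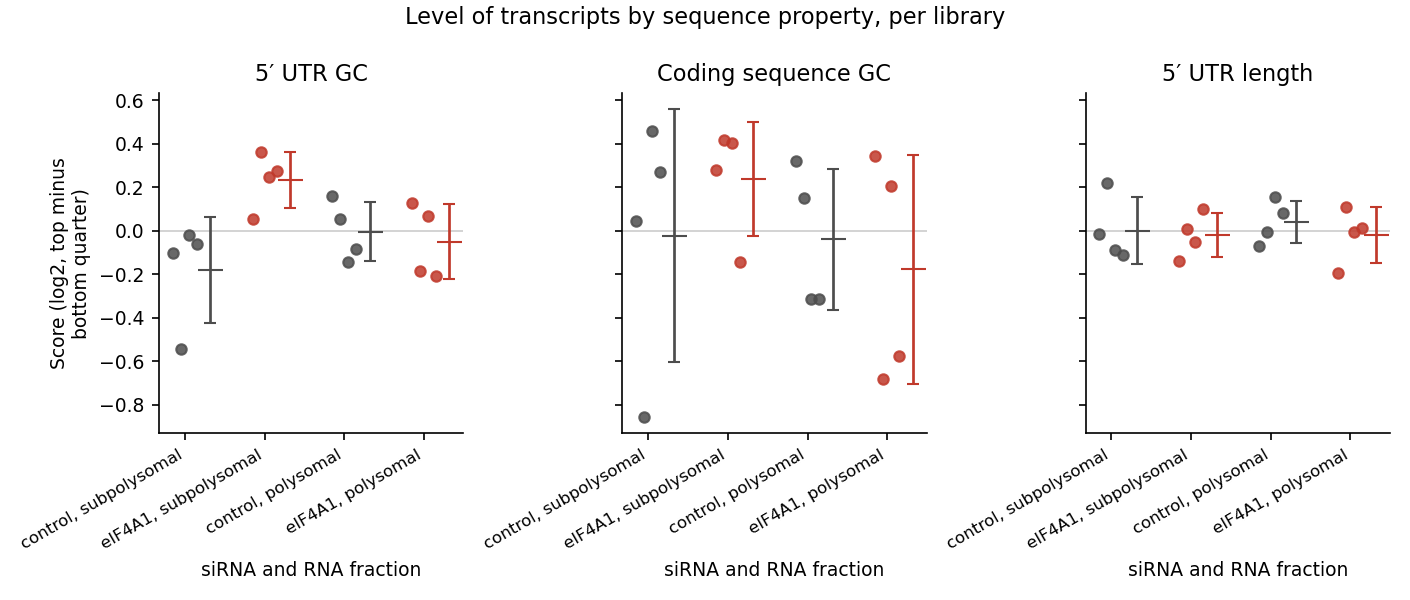
Score per library (points; log2, top minus bottom 25% of transcripts) for 5′ UTR GC, coding sequence GC and 5′ UTR length by siRNA and RNA fraction, with the mean and SD of 4 libraries. For 5′ UTR GC the eIF4A1 subpolysomal mean is 0.24 and the control subpolysomal mean −0.18, with 1 control library at −0.54.

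Across libraries, a score of GC content (mean level of genes with GC-rich minus GC-poor transcripts) rose with the implied reads in each fraction. Over 8 libraries each, Pearson's r with log implied reads was 0.897 in total, 0.921 in subpolysomal and 0.893 in polysomal RNA (exact permutation p = 0.0032, 0.00228 and 0.00424, adjusted over 3 relations p = 0.00424 each). Spearman's rho was 0.833, 0.762 and 0.929 (exact permutation p = 0.0154, 0.0368 and 0.00223, adjusted p = 0.0231, 0.0368 and 0.00669). Without the 2 libraries farthest from the median depth, r was 0.81, 0.552 and 0.834. The GC score did not differ detectably between siRNAs in total, subpolysomal and polysomal RNA. Differences were −0.14 ± 0.19, 0.10 ± 0.22 and −0.13 ± 0.28 in that order (exact permutation p = 0.486, 0.657 and 0.629).

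**Figure D5:**
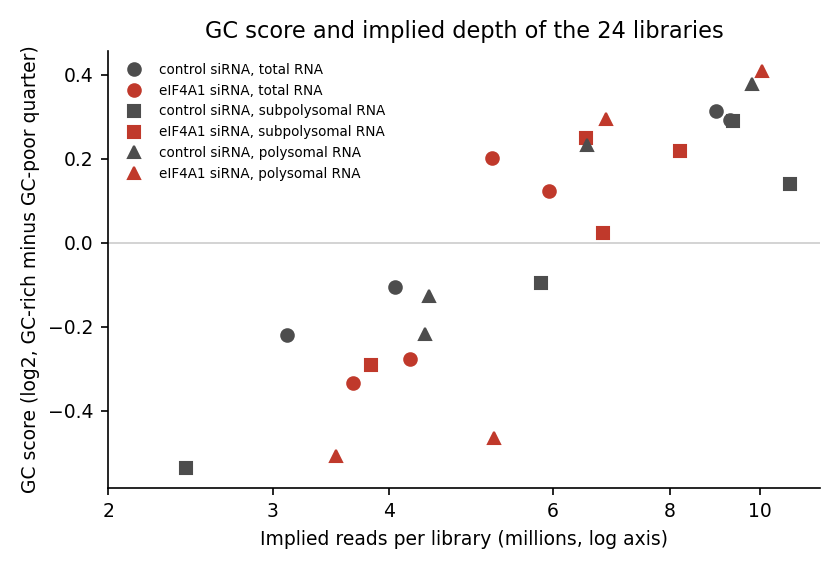
GC score of each of the 24 libraries (log2, centred within its fraction) against its implied reads on a log axis, by siRNA (colour) and fraction (shape). Scores run from −0.54 at 2420000 implied reads to 0.41 at 10100000, with both siRNAs spread along the range.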

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

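The tests chosen only after the results were seen are the exact permutation p of the 5′ UTR score, the covariate and slopes of coding sequence GC, the use of GGC repeats, mitochondrially encoded mRNAs and a single left-out library (an alternative planned before) to test an explanation, the shallowest libraries left out, and the other splits of the libraries. The matched lists, the spread between libraries and the depth covariate were set before their results were seen.

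Cytosolic ribosomal protein mRNAs shifted toward polysomal against subpolysomal RNA after knockdown, with a median difference of 0.415 on the log2 scale. The median lay at percentile 100 of 10000 lists of other genes matched for GC content, length and expression, whose own median was 0.148. The matched lists were drawn gene by gene, without the correlation between ribosomal protein mRNAs (0.807 as estimated by camera). Their spread is therefore too narrow, and the percentile cannot exclude GC content, length and expression as the cause. A difference in the relative scaling or recovery of the fractions may contribute, since mitochondrially encoded mRNAs, which cytosolic polysomes do not translate, shifted by 0.464 (SD 0.167 across the mRNAs), or 0.22 without eIF4A1 polysomal replicate 2, although quantile normalisation took them to 0.062 and left cytosolic ribosomal proteins, polysomal against subpolysomal RNA, at 0.347. The spread between libraries stays open, with a shift of the list's mean of 0.403 ± 0.3 (SE, exact permutation p = 0.208), which does not show that there was no shift. Subpolysomal replicate 1 had a mean log2 level of 12.4 under both siRNAs, against 11.4 to 11.8 in the other 6 subpolysomal libraries. This shared offset enters the SE and the p, since the exchanges did not keep equal numbers together. They also assumed no siRNA effect in either fraction. Without control subpolysomal replicate 1 the median of cytosolic ribosomal proteins was 0.223. An effect of the knockdown itself stays among the open explanations.

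Transcripts with GC-rich 5′ UTRs had a score difference between polysomal and subpolysomal RNA of −0.462 ± 0.176 (SE, exact permutation p = 0.0298, or 0.0894 adjusted over 3 properties), which does not pass. It lay mostly in subpolysomal RNA, with means of 0.235 with eIF4A1 siRNA and −0.181 with control, against −0.05 and −0.004 in polysomal RNA. As the whole cause, GC of the rest of the transcript is argued against by −0.324 ± 0.093 with the coding sequence GC score as a covariate (although the whole transcript's GC gave −0.503 ± 0.556, so that a shift specific to the 5′ UTR is not shown), a linear trend with depth by −0.465 ± 0.112 with log implied reads as a covariate (but −0.292 ± 0.173 with the shallowest library of each group left out, exact permutation p = 0.125), and a single library by −0.312, or 67.5% of the value, without control subpolysomal replicate 2 (exact permutation p = 0.0637, range 0.011 to 0.0731 over the 16 libraries left out). Slopes fitted together, per SD of each property, were −0.149 ± 0.048 for 5′ UTR GC (exact permutation p = 0.0465), −0.055 ± 0.024 for 5′ UTR length (0.0269), −0.098 ± 0.122 for 3′ UTR GC (0.463) and −0.034 ± 0.077 for coding sequence GC (exact permutation p = 0.649). A dependence of 5′ UTRs with GGC repeats on eIF4A1 cannot be told apart from none, since their shift of −0.13 ± 0.104 lies within 2 SE of 0, while it was −0.205 ± 0.069 with a mean of at least 1 (exact permutation p = 0.0461) and −0.225 ± 0.086 with the shallowest libraries left out (exact permutation p = 0.015). A dependence of GC-rich 5′ UTRs on eIF4A1 may explain the shift, as a hypothesis found and tested on the same libraries.

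Other splits of the same libraries tell whether a count is larger than other groupings of these libraries give. In total RNA, 1 of 35 splits, the real one, gave 782 or more genes, which is the smallest share that 35 splits allow. The highest other split gave 390, with eIF4A1 replicate 1 exchanged for control replicate 2. In subpolysomal RNA the real split gave 441 and the highest other 10, and in polysomal RNA 483 and 42, each with 1 of 35 splits at the real count. A chance assignment of these libraries is argued against in each fraction, at that smallest share only. The replicates may be technical and the fractions may share cultures, so a difference between single cultures is not excluded. For polysomal against subpolysomal RNA, 4 of 100 splits gave 4 or more genes, the real one included, and the highest other gave 2108. This share lies under 0.05, but 1 more such split would end that, so chance is not excluded and the share is not relied on. The count itself was 0 with a block by culture, with the shallowest libraries left out, without any 1 of the 4 control polysomal libraries, and without eIF4A1 polysomal replicate 2, 3 or 4, control subpolysomal replicate 3 or 4, or eIF4A1 subpolysomal replicate 2 or 4. For polysomal against total RNA, subpolysomal against total RNA, transcripts and 5′ UTR groups, the real count was 0 (limma). All 100 of 100 splits reach this by construction, so the splits test nothing there. An unadjusted limma p under 0.05 was found for 203, 756, 799 and 947 features, of 12587, 12271, 14860 and 17437 tested. Without any change a share of 0.05 would have one, and the first count lies under that share. By the authors' deposited posterior probability above 0.5, 3, 22, 49 and 52 passed, and the highest other splits gave 3098, 2429, 884 and 932. The splits with these high counts exchange all labels in 1 fraction, which adds the siRNA effects of both fractions and so follows the structure of the groups.

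By the test of the difference between fractions, PRKACA (−1.68), UBE2D1 (−1.54), CCNI (−1.15) and CASC3 (−1.11) passed for a different change in polysomal and subpolysomal RNA, but they fell short in 15, 16, 16 and 16 of 28 alternatives, and 0 genes passed with a block by culture (limma, against 829 genes with an unadjusted p under 0.05 and 52 by the authors' deposited posterior probability above 0.5). The lists that did so, by their medians, were initiation factors (0.244), cytosolic ribosomal proteins (0.415), other TOP mRNAs (0.399), growth factors and receptors (−0.277), mitosis and G2/M (0.182), the respiratory chain (0.191), mitochondrially encoded mRNAs (0.464) and proteasome subunits (0.232). Between polysomal and total RNA they were cytosolic ribosomal proteins (0.209), other TOP mRNAs (0.094) and mitochondrially encoded mRNAs (0.305). Between subpolysomal and total RNA they were initiation factors (−0.275), cytosolic ribosomal proteins (−0.214), other TOP mRNAs (−0.27), growth factors and receptors (0.239), the respiratory chain (−0.215) and proteasome subunits (−0.2). With an estimated correlation none of these list differences passes.

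Single libraries lay far from the other 3 of their group in 18 of 228 groups of values, where chance gives about 1 in 20, or 11.4. In total RNA, control replicate 1 had a log2 level of 1.4 for PGM1 (others 2.39 to 2.52), 4.25 for MIR503HG (3.89 to 3.92), and list means of 10.46 for cytosolic ribosomal proteins (10.18 to 10.22) and 9.12 for other TOP mRNAs (8.98 to 9.01). Control total replicate 2 had a mean of 6.9 for initiation factors (6.79 to 6.81). With eIF4A1 siRNA, total replicate 1 had 2.4 for BRINP3 (3.45 to 3.6), 3.08 for TRIM52-AS1 (3.58 to 3.66) and a mean of 6.48 for proteasome subunits (6.77 to 6.79). In subpolysomal RNA, control replicate 2 had 5.27 for CDC25B (5.68 to 5.71), 1.21 for DUSP7 (1.72 to 1.81), a 5′ UTR GC score of −0.54 (−0.1 to −0.02) and a GGC score of 0.01 (−0.2 to −0.17). Subpolysomal eIF4A1 replicate 1 had means of 12.36 for cytosolic ribosomal proteins (11.51 to 11.61) and 11.14 for other TOP mRNAs (10.47 in each), and a GGC score of −0.23 (0.06 to 0.1), while eIF4A1 replicate 3 had a mean of 4.04 for mRNAs sensitive to eIF4A or eIF4E (3.94 to 3.95). In polysomal RNA, control replicate 2 had 1.12 for MIR99AHG (1.86 to 2) and control replicate 1 a mean of 8.4 for other TOP mRNAs (8.32 to 8.34).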

How the results depend on the processing

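Alternatives with the GC score or implied reads as covariates, with the shallowest library of each group left out or with 1 library of each siRNA left out were chosen after the data were seen. EIF4A1 kept its direction and its side of the threshold in total, subpolysomal and polysomal RNA under every alternative run, and without any 1 library its log2 change stayed between −3.44 and −3.24, −3.45 and −3.28, and −4.40 and −4.01. The difference of EIF4A1, subpolysomal against total RNA, reversed to 0.556 under quantile normalisation and to 0.057 without eIF4A1 total replicate 3, with a range from −0.156 to 0.057 without any 1 library; the cause was not tested. The counts of genes moved most, in the order total, subpolysomal, polysomal. They were 57, 21 and 83 with no filter, 2087, 1335 and 1621 with precision weights, 1324, 916 and 1330 with a replicate block, 48, 23 and 44 with the shallowest libraries left out, and 146, 152 and 179 by the authors' deposited posterior probability above 0.5. The GC covariate gave 1282 in total and 1916 in polysomal RNA, and the depth covariate 2049 in polysomal RNA. Of the genes called with no filter, 31, 7 and 72 were among the 782, 441 and 483. The cause of these moves was not tested. With precision weights 776, 439 and 480 of the genes called were shared with the 782, 441 and 483, and with the block 769, 436 and 483. The share of rises in subpolysomal RNA was 68% and 57.8% under quantile normalisation.

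For polysomal against subpolysomal RNA the count of 4 became 9 under quantile normalisation, 80 with precision weights, 10 with a replicate block, 0 with a block by culture, 17 with the GC covariate, 18 with the depth covariate, 0 with the shallowest libraries left out and 52 by the authors' probability. For polysomal against total RNA the count of 0 became 8 with no filter, 1 under quantile normalisation, 2 with precision weights, 1 with either covariate and 3 by the authors' probability. For subpolysomal against total RNA it became 9 with no filter, 43 with precision weights, 3 with a block by culture, 2 with the GC covariate and 22 by the authors' probability. For transcripts it became 21 with no filter, 6 under quantile normalisation, 10 with precision weights, 2 with a replicate block, 1 with the depth covariate, 2 with the shallowest libraries left out and 49 by the authors' probability. For 5′ UTR groups it became 17, 4, 1 and 2 in the first 4 of these, 2 with the GC covariate, 1 with the shallowest libraries left out and 52 by the authors' probability. The cause was not tested.

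Without any 1 library, counts ran from 198 to 2077 in total RNA (lowest without eIF4A1 replicate 4, highest without eIF4A1 replicate 1), from 71 to 848 in subpolysomal RNA (without eIF4A1 replicates 2 and 1) and from 97 to 1033 in polysomal RNA (without control replicate 4 and eIF4A1 replicate 1). They ran from 0 to 10 for polysomal against subpolysomal RNA, from 0 to 1 for polysomal against total RNA (1 without eIF4A1 polysomal replicate 1) and from 0 to 2 for subpolysomal against total RNA (1 and 2 without control and eIF4A1 subpolysomal replicate 1). For transcripts they ran from 0 to 7 and for 5′ UTR groups from 0 to 3; without control subpolysomal replicate 2, 3 and 4 and eIF4A1 subpolysomal replicate 2 and 3, they were 1, 2, 4, 2 and 7 for transcripts and 0, 2, 3, 1 and 3 for the groups. With 1 library of each siRNA left out in all 16 ways, the medians were 85, 27.5 and 82.5 genes in total, subpolysomal and polysomal RNA, with ranges of 17 to 2240, 2 to 1146 and 23 to 497, so the shallowest libraries left out are not unusual among them.

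Lists past the test were 10 with no filter and 11 with a replicate block in subpolysomal RNA, 1 under quantile normalisation in polysomal against total RNA, and 0 in each of the 6 comparisons with an estimated correlation. Without any 1 library they numbered 9 to 13 in total, 3 to 7 in subpolysomal and 9 to 13 in polysomal RNA, and 5 to 9, 2 to 7 and 5 to 8 in polysomal against subpolysomal, polysomal against total and subpolysomal against total RNA. Of 141 results of named genes, 2877 alternatives were run, of which 2177 kept direction and side of the threshold, 697 kept the direction but fell short of it, 1 passed it newly and 2 reversed. CA2, CA12 in total and polysomal RNA, CDC25B, GIT1 and OSTC in subpolysomal RNA, and ID1, RBM24, SLC7A11, TP53INP1 and UBE2D1 in polysomal RNA passed under every alternative run for them. PRKACA, UBE2D1, CCNI and CASC3, polysomal against subpolysomal RNA, fell short in 15, 16, 16 and 16 of 28. List calls also ended for cholesterol synthesis in subpolysomal RNA with the shallowest libraries left out (adjusted p = 0.0727), and for mitochondrially encoded mRNAs with them left out in polysomal RNA (0.153) and polysomal against total RNA (0.0804) and with the GC covariate in polysomal RNA (0.104). In polysomal against subpolysomal RNA they ended for mitosis with a mean of at least 1 (0.0745), the GC covariate (0.405) or the shallowest libraries left out (0.148), for initiation factors with the GC covariate (0.0534) and for growth factors with the shallowest libraries left out (0.0609). Medians of lists that still passed moved by over 1.5 times with the shallowest libraries left out for the ATF4 response (−0.229 in total and −0.241 in subpolysomal RNA), and in polysomal RNA for growth factors (−0.21) and cholesterol synthesis (−0.156). They did so with the GC covariate in polysomal RNA for mitosis (0.103) and cholesterol synthesis (−0.132) and in subpolysomal against total RNA for proteasome subunits (−0.122). For the lists past the test in the comparisons given first, 927 alternatives kept their side and 101 fell short. Lists that passed only in an alternative are not in this tally. The 5′ UTR differences ran from −0.14 to 0.044 for length, −0.516 to −0.312 for GC and −0.219 to −0.083 for GGC repeats without any 1 library, and GGC repeats gave −0.37 with no filter. For 5′ UTR GC the alternatives fixed before gave −0.328 ± 0.102 with a split at the median (exact permutation p = 0.0122), −0.423 ± 0.154 with a mean of at least 1 (0.0204), −0.43 ± 0.185 with a posterior SD of at most 0.5 (0.0384) and −0.42 ± 0.682 with no filter (0.522), unadjusted over properties. A library of the other siRNA with the same number was the closest in 4 of 8 cases in each fraction, where chance gives 2, so the numbers may mark a partial batch, as the counts of 1324, 916 and 1330 with a replicate block leave open. Reads per feature are not known, and the depth limit on low features cannot be stated in counts.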

Other observations

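The counts in all fractions and at other levels, the test of the GC score on highly expressed genes and the choice of named genes in this part were set after the data were seen, while the siRNA and equal-number tests of the GC score were set before their results.

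Some genes changed in all 3 fractions. Of 11378 genes tested in each, 25 rose in all 3 and 79 fell in all 3. Among those that rose, chosen after their values were seen, was BAG1, which encodes a co-chaperone of the heat shock protein HSP70, with 0.77, 1.01 and 0.56 on the log2 scale in total, subpolysomal and polysomal RNA. DUSP7 rose by 0.97, 1.74 and 0.82 and TOMM40 by 0.82, 1.75 and 0.58. CA12, a carbonic anhydrase induced by estrogen, fell in all 3, with −1.11, −0.99 and −1.27.

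At the transcript level fewer features passed than genes (limma). Of 21963 transcripts tested in total RNA, 6 fell and 0 rose, with 3316 at an unadjusted p under 0.05 and 145 by the authors' deposited posterior probability above 0.5. In subpolysomal RNA 3 of 14186 rose and 1 fell, and in polysomal RNA 6 of 18818 rose and 35 fell. Of 22251 5′ UTR groups in total RNA, 7 fell and 0 rose, with 3422 at an unadjusted p under 0.05 and 156 by the authors' probability. Between polysomal and total RNA 0 of 20734 groups passed (limma), with 495 at an unadjusted p under 0.05 and 9 by the authors' deposited posterior probability above 0.5. Between polysomal and subpolysomal RNA the transcripts with the smallest p belonged to CASC3 (−1.17 ± 0.18, SE), MKNK2 (−1.48 ± 0.22), PCBP2 (−1.31 ± 0.21) and PRKACA (−1.87 ± 0.30), each with an adjusted p of 0.108, named here after their values were seen.

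The GC score of the libraries follows their implied reads in each fraction. Few reads behind low-expressed genes are argued against as the whole cause, since among highly expressed genes the smallest of the 3 correlations was 0.865. The siRNA, the biological explanation the design gives, is argued against as well, since the smallest correlation within siRNA groups was 0.889. A batch shared by the same-numbered libraries of the 2 siRNAs within a fraction is argued against as the whole cause by a correlation of −0.007 over the 12 such pairs, and a batch shared across fractions was not tested. Another difference between libraries, in amplification for example, may lie behind the relation, but the labels give no batch and it was not tested.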
